A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

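Total RNA of yeast cells with the SAN1 gene and of san1 mutant cells was compared directly on 12 2-channel arrays, per the labels, 6 in each of 2 media. Arrays 1 to 3 of a medium carried the SAN1 RNA in channel 1 and arrays 4 to 6 the san1 RNA. The descriptions of YC arrays 1 to 3 name YEPD, whereas their titles and source names give YC, which was followed. The deposited table holds 1 log ratio per array and spot, taken as log2, already centred by the authors, with medians of the 12 columns between -0.0029 and 0.0033. The scanner, the background correction, the normalization, the filters behind the empty cells and the log base are not given in the sources used here. The direction of the ratio was taken from the SAN1 row, by a rule fixed before the data were examined. Its deposited value was -4.57 to -3.67 on arrays with the SAN1 RNA in channel 1 and 2.69 to 3.89 on the others, so the table was read as channel 2 over channel 1. A base of 10 was set aside as implausible for values of this size. The natural logarithm could not be told from base 2.

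The column medians as deposited were 0.0011, -0.0029, 0, -0.0018, -0.0004 and -0.0009 on YEPD arrays 1 to 6 and 0.0033, -0.0008, -0.0024, -0.0027, -0.0007 and 0.0011 on YC arrays 1 to 6. The SD of the log ratios was 0.153 to 0.201. On YC arrays 1 and 4, 6.15% and 7.42% of the values equalled another gene's value on the same array, against 0.7% to 2.56% elsewhere. The table had 6204 rows, of which 5704 matched a locus tag of the RefSeq gene table for assembly R64, 42 matched through a synonym, and 458 kept the file's name. The assembly was used for names and gene order only. Rows of the same gene were averaged (27 genes), which left 6177 genes.

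Each array was centred on its median and turned so that positive values mean higher in san1. Genes needed at least 2 values in each dye orientation of each medium, which left 5890 and removed 287. 4652 genes had values on all 12 arrays. A linear model with a mean per medium and 1 dye term common to both media was fitted per gene by least squares, with limma 3.58.1 in R 4.3.3 moderating the variances (prior degrees of freedom 3.76, residual degrees of freedom 9 for a complete gene). Genes with empty cells were fitted exactly on their own values. The dye term passed for 964 genes (16.4%). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The contrasts were YEPD, YC, YC minus YEPD, and the mean of both.

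Before the data were examined, 49 gene lists were fixed, and 47 with at least 5 measured members were tested with limma's cameraPR at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the residuals (negative estimates set to 0). 12 lists passed in YEPD, 16 in YC, 16 for the difference and 18 over both media, of which 5, 3, 2 and 3 kept their call with an estimated correlation. Among those kept, the estimates for the ergosterol list (0.00854) and the thiamine and vitamin B6 list (-0.0178) lay below the preset. For these lists the second test was thus no stricter than the first. Genes were named by a rule fixed beforehand. It takes SAN1, the 12 risen and 12 fallen genes with the largest change among those called with the same sign on every measured array (for the difference, the 12 largest each way), up to 4 called members with the lowest p of each list that passed or had at least 3 called members, and the members of the lists of neighbours, mating-type specific and marker genes as values. Text space allowed only part of the list members to be named.

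The fit was tested on simulated arrays of 5890 genes with the observed empty cells, spread and dye terms and 200 changed genes. For the change in YEPD, 69.7% of genes changed by 0.2 and 100% of those changed by 0.4 were recovered, for the change in YC 69.7% and 90.9%, and for the difference between media 41.2% and 84.8%. False calls made up 3.91%, 6.3% and 4.5% of calls. The simulated noise was independent between arrays and between genes. These shares therefore hold only if each array is a separate replicate, which the labels do not say.

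Alternatives covered the centring and scaling between arrays, the dye term, the arrays entering the fit, the array number as a block, averaging arrays n and n plus 3, the filter on empty cells, rows of the same gene, the variance model, a size threshold, the sign of arrays 4 to 6, and each array left out. YEPD arrays 4 and 6 were closer to each other (SD of their difference 0.106, 0 equal values) than the other same-orientation YEPD arrays (0.154 to 0.174), and stayed separate replicates, with their average as an added alternative.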

Results

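RNA of budding yeast cells carrying the SAN1 gene was hybridized together with RNA of san1 mutant cells on each of 12 2-channel arrays. Cells had grown in YEPD, a rich medium, for 6 arrays and in the medium the labels call YC for the other 6. SAN1 encodes a ubiquitin ligase of the nucleus that marks misfolded proteins for destruction by the proteasome. In each medium, 3 arrays carried the SAN1 RNA in channel 1 and 3 carried the san1 RNA there, so that the dyes were balanced between the strains. An array held between 5836 and 6180 log ratios, and 5890 genes had enough values to be tested. All changes are given as the log2 ratio of san1 over SAN1, positive where a transcript was higher in the mutant. The table does not state the base of its logarithm, and base 2 was assumed here. Were it the natural logarithm, the folds below would be larger and more genes would reach 1.5-fold, with the same signs and tests. No label says that the arrays came from separate cultures, so the p-values measure the spread between these arrays, part of which is technical if they did not.

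SAN1 itself was far lower in the mutant RNA on 12 of 12 arrays. The fitted change was -3.78 in YEPD (SE 0.15, n = 6 arrays, adjusted p = 2.2e-08) and -3.74 in YC (SE 0.15, n = 6 arrays, adjusted p = 2.5e-08). These are a 13.7-fold and a 13.4-fold decrease. Single arrays lay between -3.94 and -3.39 in YEPD and between -4.57 and -2.69 in YC. The media did not differ in this value beyond the spread (difference 0.03, SE 0.22, adjusted p = 0.94). The same row had been used to settle which channel is the numerator, so its sign is no independent check of the labels. It does run one way on all arrays of each dye orientation. Among the genes next to SAN1, PEX7, encoding a peroxisomal import receptor, was lower on 12 of 12 arrays (-0.20, SE 0.03, adjusted p = 0.002 in YEPD and -0.27, SE 0.03, adjusted p = 0.00012 in YC). MKC7, a GPI-anchored protease gene, fell in YC (-0.32, SE 0.041, adjusted p = 0.00027) and stood at -0.04 in YEPD (adjusted p = 0.84). DOP1 was measured on 5 YC arrays and passed there (-0.14, SE 0.045, adjusted p = 0.036). This call was lost without YC array 6 (-0.08, adjusted p = 0.2), YC array 3 (-0.13, adjusted p = 0.1) or YEPD array 5 (-0.14, adjusted p = 0.051). TAF12 stood at 0.06 in YEPD and 0.05 in YC and passed in neither.

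In YEPD, copper and iron uptake genes, cytochrome genes and sterol genes were among the transcripts that rose in san1 cells. FRE7, a copper-responsive metalloreductase gene, was 1.97-fold higher (log2 0.98, SE 0.039, adjusted p = 4.6e-08, above 0 on 6 of 6 arrays). CTR1, the high-affinity copper transporter, rose by 0.56 (SE 0.046, adjusted p = 5.5e-05), and FRE1, a surface reductase for iron and copper, by 0.49 (SE 0.044, adjusted p = 6e-05). YPR123C, a reading frame adjacent to CTR1, rose by 0.67 (SE 0.054, adjusted p = 5.5e-05), on 6 of 6 arrays as well. Cytochrome b5 (CYB5) rose by 0.52 (SE 0.058, adjusted p = 0.00025), cytochrome c (CYC1) by 0.46 (SE 0.071, adjusted p = 0.0027) and the flavohemoglobin gene YHB1 by 0.41 (SE 0.034, adjusted p = 4.4e-05), each on 6 of 6 arrays.

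Other transcripts higher in YEPD were the reading frames YGR164W (0.55, SE 0.054) and YDR278C (0.38, SE 0.08, measured on 5 arrays). ASP3-3 (0.39, SE 0.037) belongs to a set of near-identical asparaginase genes whose probes can read each other's RNA. The transcript that fell most after SAN1 was NCE103, encoding carbonic anhydrase (-0.72, SE 0.1, adjusted p = 0.0011, below 0 on 6 of 6 arrays). It was followed by CIS1 (-0.41, SE 0.062, measured on 4 arrays), YLR108C (-0.34, SE 0.037) and TIR1, a cell wall mannoprotein gene (-0.32, SE 0.051). Smaller decreases were found for the oxysterol-binding protein gene HES1 (-0.26), MIX17 (-0.25), the serine deaminase gene CHA1 (-0.24) and the acyltransferase gene ALE1 (-0.23). The hypoxic gene ANB1 (-0.23), the peroxiredoxin gene AHP1 (-0.21) and the ceramide synthase gene LAC1 (-0.21) also fell. Each gene named here had the same sign on every array that measured it.

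Several gene lists fixed before the data were examined moved in YEPD. The 7 measured helicase genes of the subtelomeric Y' elements all rose, 7 also when adjusted over the list alone, by a median of 0.25. The list test gave adjusted p = 5.06e-19, and adjusted p = 3.28e-07 with an estimated correlation. YRF1-1 rose by 0.28 (SE 0.038), YRF1-5 by 0.26 (SE 0.034), YRF1-2 by 0.25 (SE 0.027) and YRF1-6 by 0.21 (SE 0.027). These genes are close copies, so their probes can read each other's RNA. Of 274 genes among the 10 outermost of each chromosome end, 40 rose, 1 fell and 233 did not pass (50 rose and 2 fell when adjusted over the list alone, adjusted p = 5.88e-05 with an estimated correlation). Of the 40, 36 lay among the outermost 1 to 4 genes of an end, and YFL066C (0.33, SE 0.039) and YBL113C (0.25, SE 0.029) were examples. This list holds the 7 Y' helicase genes, and these 2 reading frames lie in Y' elements as well, so part of it counts the same signal again. Without them and YJL225C, 30 of 264 rose and 1 fell, and the list test gave an unadjusted p of 4.83e-10, or 0.000115 with an estimated correlation. Only these genes were left out, so other frames of Y' elements may remain among the 264 and carry part of that signal. Of 25 ergosterol synthesis genes, 8 rose, 1 fell and 16 did not pass (12 and 2 when adjusted over the list alone, adjusted p = 5.22e-07 with an estimated correlation). Examples were ERG28 (0.44, SE 0.044), HMG1 (0.43, SE 0.058), the HMG-CoA reductase gene, ERG2 (0.37, SE 0.038) and ERG27 (0.18, SE 0.027). Of 25 Hsf1-dependent chaperone genes, 5 rose and 20 did not pass (11 rose when adjusted over the list alone, adjusted p = 3.84e-07 with an estimated correlation). They included the near-identical Hsp70 genes SSA1 (0.34, SE 0.055) and SSA2 (0.27, SE 0.051), the small heat shock gene HSP26 (0.31, SE 0.062) and the co-chaperone gene STI1 (0.19, SE 0.041, above 0 on 5 of 6 arrays). Of 22 thiamine and vitamin B6 genes, the thiamine transporter gene THI7 rose (0.16, SE 0.032), also when adjusted over the list alone, and 21 did not pass (adjusted p = 0.0026 with an estimated correlation).

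For 7 further lists the call in YEPD was lost with an estimated correlation. Of 16 COS and DUP family genes, which are close copies, COS8 rose by itself (0.15, SE 0.035), 1 also when adjusted over the list alone (adjusted p = 0.672 with an estimated correlation). Of 22 seripauperin (PAU) genes, which are close copies as well, 0 passed in limma, also 0 when adjusted over the list alone, and 7 had an unadjusted p under 0.05 (adjusted p = 0.398 with an estimated correlation). The other 5 lists were shifted downward, with medians of -0.04 to -0.02 and 0 members passing in limma, over all genes or adjusted over the list alone. They were 135 cytosolic ribosomal protein genes (adjusted p = 0.979 with an estimated correlation), 71 mitochondrial ribosomal protein genes (0.979), 74 ribosome biogenesis genes (0.979), 44 proteasome genes (0.672) and 12 daughter-specific genes (0.672). Of their members, 14, 2, 0, 2 and 0 had an unadjusted p under 0.05. The 33 general stress genes did not shift in YEPD (median 0.02, adjusted p = 0.773). Nor did the lists of metal genes as a whole, despite FRE7, CTR1 and FRE1. Of 23 iron regulon genes 2 rose and 21 did not pass (2 rose and 1 fell when adjusted over the list alone, list test adjusted p = 0.773), and of 13 zinc and copper genes 1 rose and 12 did not pass (1 when adjusted over the list alone, list test adjusted p = 0.987).

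In limma's fit, 120 of 5890 genes passed an adjusted p of 0.05 in YEPD (2.04%), 101 higher and 19 lower, with a median size of 0.26. Of these, 4 changed by at least 1.5-fold: FRE7, YPR123C, NCE103 and SAN1. It would be 13 were the values natural logarithms. Arrays 1 and 4, 2 and 5, and 3 and 6 were also averaged, as if each pair held the same RNA, which the labels do not say. This left 65 genes, 63 of them among the 120. It ended the calls of SSA1 (adjusted p = 0.066), HSP26 (0.12), SSA2 (0.14), STI1 (0.062), ERG27 (0.052), THI7 (0.16), COS8 (0.24), PEX7 (0.062) and YDR278C (0.24). Leaving out a single array also ended some of these calls and that of HES1. The highest adjusted p was 0.15 for YDR278C without YEPD array 1, 0.091 for HSP26 without array 3, 0.059 for HES1 and 0.22 for COS8 without array 4. Without array 6 it was 0.063 for SSA2, 0.13 for STI1 and 0.1 for THI7.

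In YC, stress and chaperone genes were among the transcripts that rose most in san1 cells, as were CYB5, YHB1 and CYC1, already named for YEPD. HSP12, a membrane-associated stress protein gene, was 2.06-fold higher (log2 1.04, SE 0.098, adjusted p = 4.5e-05) and HSP26 1.95-fold higher (log2 0.96, SE 0.062, adjusted p = 2.3e-06), both on 6 of 6 arrays. On as many arrays, CYB5 rose by 0.78 (SE 0.058, adjusted p = 7.3e-06), YHB1 by 0.69 (SE 0.034, adjusted p = 1.4e-07) and CYC1 by 0.67 (SE 0.071, adjusted p = 8.6e-05). After SAN1, and among genes below 0 on every array that measured them, the transcripts that fell most were EEB1, an ethyl ester synthase gene (-0.53, SE 0.044, adjusted p = 1.3e-05), and PHD1, a transcription factor gene of filamentous growth (-0.49, SE 0.035, adjusted p = 6.9e-06). The phosphate transporter gene PHO89 (-0.45, SE 0.043) and MMO1 (-0.44, SE 0.06, measured on 5 arrays) followed. NCE103 (-0.54), above 0 on YC array 4, was named after its value was seen.

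Further rises in YC were those of RTC3 (0.61, SE 0.099), MSC1 (0.56, SE 0.054), ERG28 (0.53, SE 0.044), the inducible Hsp70 gene SSA4 (0.53, SE 0.043). The cytosolic catalase gene CTT1 (0.51, SE 0.096, measured on 5 arrays), STF2 (0.49, SE 0.052) and the disaggregase gene HSP104 (0.46, SE 0.084) also rose. Further decreases were those of FIT3, a cell wall protein gene of siderophore uptake (-0.41, SE 0.085), the zinc transporter genes ZRT1 (-0.40, SE 0.076) and ZRT3 (-0.35, SE 0.086), and YLR108C (-0.39, SE 0.037). The methionine permease gene MUP1 (-0.37, SE 0.034), the siderophore transporter gene ARN1 (-0.36, SE 0.08), YGL088W (-0.36, SE 0.1) and EOS1 (-0.35, SE 0.031) fell too. FRE7 (-0.16, adjusted p = 0.021), CTR1 (-0.22, adjusted p = 0.0098) and FRE1 (-0.28, adjusted p = 0.0011), which had risen in YEPD, fell in YC, each on all arrays that measured it.

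**Figure D1:**
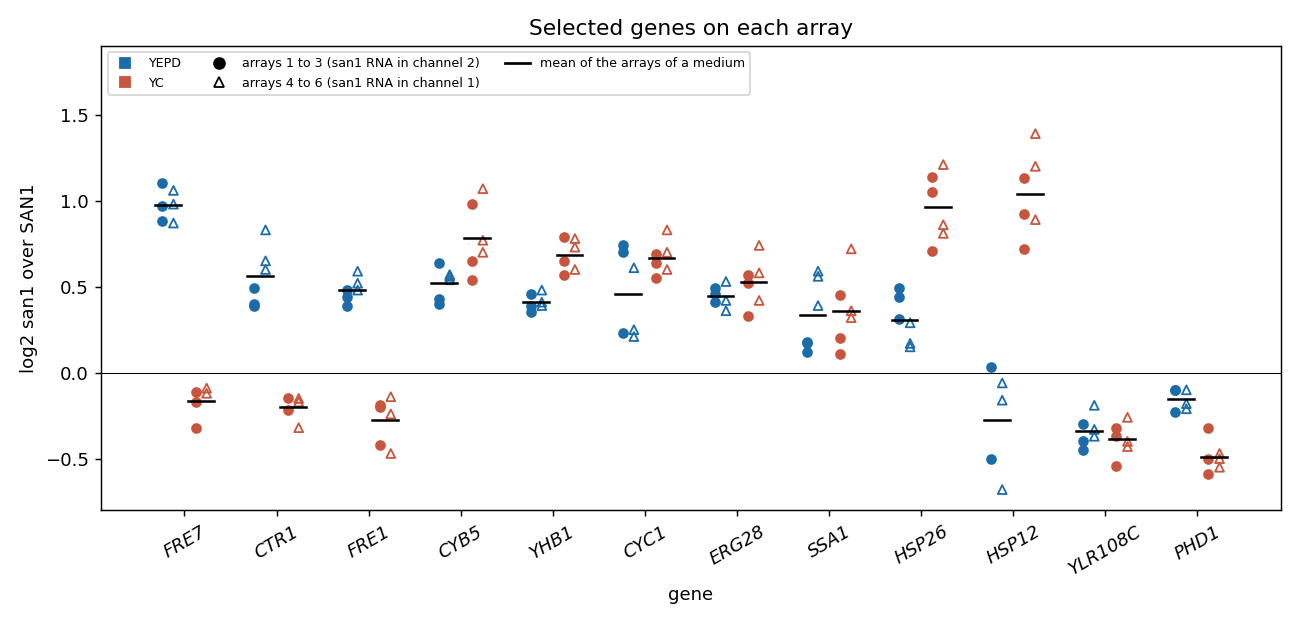
Log2 ratio of san1 over SAN1 (vertical axis) of 12 genes (horizontal axis) on each array, blue for YEPD and red for YC, filled circles for arrays 1 to 3, open triangles for arrays 4 to 6, with a black bar at the mean of the arrays of a medium. FRE7, CTR1 and FRE1 lay above 0 on the YEPD arrays and below 0 on the YC arrays, while CYB5, YHB1, CYC1 and ERG28 lay above 0 on the arrays of both media.

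Chaperones, Y' helicases and sterol genes were the lists whose shift in YC held with an estimated correlation. For the sterol genes the estimate (0.00854) lay below the preset of 0.01. Of 25 Hsf1-dependent chaperone genes, 15 rose and 10 did not pass (17 rose when adjusted over the list alone, median 0.25, adjusted p = 2.94e-07 with an estimated correlation). Examples were the Hsp90 gene HSC82 at 0.42 (SE 0.053) and CPR6, a cyclophilin gene, at 0.31 (SE 0.034). The list median was above 0 on 12 of 12 arrays. The 7 Y' helicase genes rose, as in YEPD (median 0.29, 7 when adjusted over the list alone, adjusted p = 0.00254 with an estimated correlation). YRF1-6 stood at 0.34 (SE 0.027) and YRF1-2 at 0.33 (SE 0.027). Of 25 ergosterol genes, 13 rose, 5 fell and 7 did not pass (13 and 6 when adjusted over the list alone, adjusted p = 0.0446 with an estimated correlation). ERG20 stood at 0.29 (SE 0.031) and ERG27 at 0.24 (SE 0.027).

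General stress genes rose in YC as a group, unevenly over the arrays. Of 33 measured, 17 rose, 0 fell and 16 did not pass in limma's fit (18 rose when adjusted over the list alone), with a median of 0.23, and the list test lost its call with an estimated correlation (adjusted p = 0.345). STF2, PNC1, the nicotinamidase gene (0.36, SE 0.056), and NTH1, the neutral trehalase gene (0.27, SE 0.043), were examples besides HSP12. The list's median was -0.02, 0.53, 0.28, -0.04, 0.52 and 0.24 on YC arrays 1 to 6. Ribosome biogenesis genes moved the other way, with medians of 0.17, -0.17, -0.05, 0.22, -0.19 and -0.06 on the same arrays. Arrays 1 and 4, 2 and 5, and 3 and 6 thus lay close together in both lists. Across genes, deviations from the mean of a medium and orientation correlated at 0.37, 0.52 and -0.22 for these YC pairs. Other YC pairs of opposite orientation lay between -0.69 and 0.29. In YEPD the same pairs were at 0.37, 0.23 and 0.03, and the others between -0.31 and 0.07. Arrays 3 and 6 thus did not stand out as a pair in either medium.

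**Figure D2:**
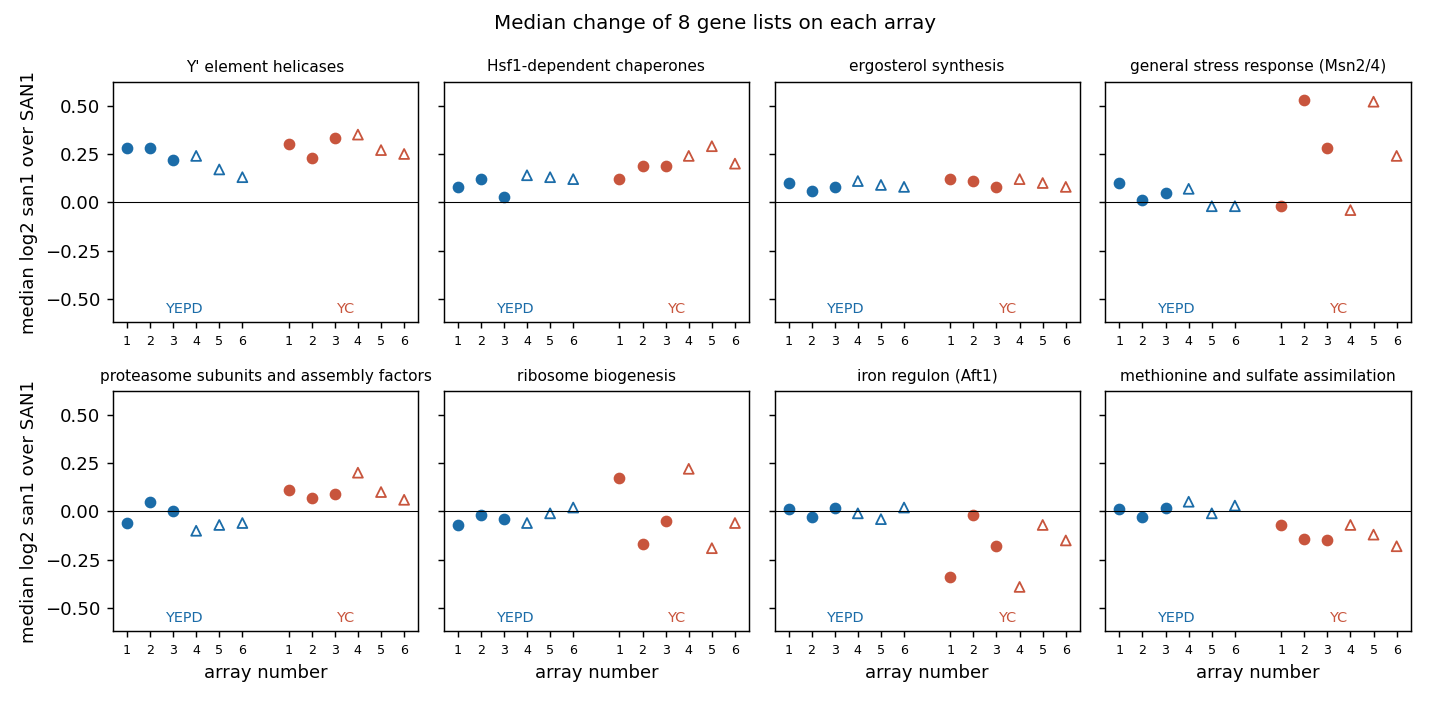
Median log2 ratio of san1 over SAN1 (vertical axis) of 8 gene lists on each array (horizontal axis, array numbers 1 to 6 of each medium), blue for YEPD and red for YC, filled circles for arrays 1 to 3 and open triangles for arrays 4 to 6. Y' helicases, Hsf1-dependent chaperones and ergosterol genes lay above 0 on 12 of 12 arrays, and the general stress median ranged from -0.04 to 0.53 over the YC arrays.

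The proteasome, mitochondrial ribosome, histone and histidine lists rose in YC in tests whose call was lost with an estimated correlation. Of 44 proteasome genes, 20 rose and 24 did not pass (24 rose when adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). RPN8 was at 0.35 (SE 0.048) and RPN5 at 0.28 (SE 0.033), both of the regulatory particle. Of 71 mitochondrial ribosomal protein genes, 19 rose and 52 did not pass (25 rose when adjusted over the list alone, adjusted p = 0.443 with an estimated correlation). MRPS16 was at 0.24 (SE 0.036). The list was made by name pattern, so it also holds MRP8 (0.34, SE 0.066), whose product is not a known protein of that ribosome. Of 10 histone genes, 5 rose and 5 did not pass (7 rose when adjusted over the list alone, adjusted p = 0.415 with an estimated correlation). Examples were the histone H4 genes HHF2 (0.30, SE 0.057) and HHF1 (0.27, SE 0.051), whose sequences are close. Of 7 histidine biosynthesis genes, HIS7 (0.18, SE 0.025), HIS4 (0.16, SE 0.028) and 1 other rose (4 when adjusted over the list alone, adjusted p = 0.187 with an estimated correlation).

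Genes of metal, phosphate and amino acid uptake fell in YC, again in list tests whose call was lost with an estimated correlation. Of 23 iron regulon genes, 13 fell and 10 did not pass (14 fell and 1 rose when adjusted over the list alone, adjusted p = 0.191 with an estimated correlation). ARN2 was at -0.31 (SE 0.057). The list's median was -0.34, -0.02, -0.18, -0.39, -0.07 and -0.15 on arrays 1 to 6, again alike in arrays 1 and 4, 2 and 5, and 3 and 6. Of 27 methionine and sulfate genes, 14 fell and 13 did not pass (14 when adjusted over the list alone, adjusted p = 0.0909 with an estimated correlation). The S-methylmethionine permease gene MMP1 was at -0.28 (SE 0.046). Of 20 amino acid permease genes, 11 fell and 9 did not pass (11 when adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). TAT1 was at -0.27 (SE 0.03) and GNP1 at -0.26 (SE 0.037). Of 20 phosphate response genes, 10 fell, 2 rose and 8 did not pass (11 and 2 when adjusted over the list alone, adjusted p = 0.132 with an estimated correlation). The vacuolar phosphatase gene PHO8 was at -0.27 (SE 0.033). Of 21 multidrug resistance genes, 10 fell and 11 did not pass (11 fell and 1 rose when adjusted over the list alone, adjusted p = 0.124 with an estimated correlation). The drug transporter gene PDR5 was at -0.29 (SE 0.036) and IPT1 at -0.22 (SE 0.03). Of 13 zinc and copper genes, 6 fell and 7 did not pass (8 when adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). ADH4 was at -0.33 (SE 0.069). Arrays 1 and 4 stood apart for these metal genes: ADH4 was at -0.58 and -0.71 on them, against -0.23 to -0.14 elsewhere. Without both, the change was -0.17 for ADH4, -0.22 for ZRT1, -0.15 for ZRT3, -0.17 for ARN1, -0.19 for ARN2 and -0.27 for FIT3, each still called. Of 12 daughter-specific genes, 5 fell and 7 did not pass (7 when adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). SUN4 was at -0.23 (SE 0.033) and DSE4 at -0.22 (SE 0.039). Of 22 PAU genes, 4 fell and 18 did not pass (3 when adjusted over the list alone, adjusted p = 0.203 with an estimated correlation). PAU15 (-0.14, SE 0.028, measured on 5 arrays) and PAU17 (-0.14, SE 0.032) were examples.

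In limma's fit, 1462 of 5890 genes passed in YC (24.8%), 765 higher and 697 lower, with a median size of 0.16. Of these, 7 changed by at least 1.5-fold: HSP12, HSP26, CYB5, YHB1, CYC1, RTC3 and SAN1. It would be 32 were the values natural logarithms. The count of called genes was 928 when the YC arrays were fitted alone and 816 with arrays 1 and 4, 2 and 5, and 3 and 6 averaged, 789 of them among the 1462. This average ended the calls of ARN1 (adjusted p = 0.053), ZRT3 (0.063), YGL088W (0.05) and PAU15 (0.069). YGL088W also lost its call without YC arrays 1 and 4 (-0.21, adjusted p = 0.16) and without single arrays, with an adjusted p of 0.07 at most, without YC array 3.

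The difference between the media was tested gene by gene. Stress genes, led by HSP12, and the copper and iron uptake genes FRE7, CTR1 and FRE1 were among the genes that differed most. FRE7 was at 0.98 in YEPD and -0.16 in YC (difference -1.14, SE 0.059, adjusted p = 1.6e-06), and CTR1 at 0.56 and -0.22 (-0.78, SE 0.068, adjusted p = 2e-04). FRE1 was at 0.49 and -0.28 (-0.76, SE 0.062, adjusted p = 5.2e-05), and YPR123C at 0.67 and -0.11 (-0.78, SE 0.08, adjusted p = 0.00089). In the other direction, HSP12 was at -0.28 in YEPD and 1.04 in YC (1.33, SE 0.15, adjusted p = 0.0011), and HSP26 at 0.31 and 0.96 (0.66, SE 0.088, adjusted p = 0.0031). RTC3 was at -0.02 and 0.61 (0.62, SE 0.14, adjusted p = 0.02), and STF2 at -0.10 and 0.49 (0.59, SE 0.074, adjusted p = 0.0021).

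Larger in YC were also the changes of MSC1 (0.54, SE 0.076), FMP16 (0.51, SE 0.12), CTT1 (0.50, SE 0.14), STF1 (0.48, SE 0.11). The proteasome subunit gene SEM1 (0.47, SE 0.1), the protease inhibitor gene PBI2 (0.47, SE 0.085), YCR097W-A (0.46, SE 0.081), at the silent mating-type locus whose sequence has copies, and MTD1 of folate metabolism (0.44, SE 0.082) followed. Lower in YC than in YEPD were the changes of YCL046W (-0.51, SE 0.11), EEB1 (-0.44, SE 0.063), PHO89 (-0.44, SE 0.061), the arsenite transporter gene ARR3 (-0.41, SE 0.064). IRC7 (-0.40, SE 0.062), YDL096C (-0.40, SE 0.085), the low-affinity iron transporter gene FET4 (-0.38, SE 0.11) and YGR164W (-0.38, SE 0.081) followed. FET4 was at -0.70 and -0.60 on YC arrays 1 and 4, against -0.17 to -0.01 on the other YC arrays, and its difference was -0.20 without these arrays (adjusted p = 0.031).

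Among the lists, Hsf1-dependent chaperones shifted upward from YEPD to YC (5 of 25 higher, 20 not passing, 6 higher when adjusted over the list alone, adjusted p = 0.0267 with an estimated correlation). SSA4 was at 0.40 (SE 0.06). Thiamine and vitamin B6 genes, some of them close copies, shifted downward (2 of 22 lower, 2 when adjusted over the list alone, adjusted p = 0.00937 with an estimated correlation). These were THI7 (-0.17) and THI13 (-0.20). THI13 lost its call in limma's fit without YC arrays 1 and 4 (-0.19, adjusted p = 0.071).

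The other 14 lists lost their call with an estimated correlation, and the p-values given for them are those of that test. Proteasome genes shifted upward (14 of 44 higher, 20 when adjusted over the list alone, adjusted p = 0.0952 with an estimated correlation), with RPN8 at 0.35 and RPN5 at 0.32. So did mitochondrial ribosomal protein genes (15 of 71, 18 when adjusted over the list alone, adjusted p = 0.449), with RSM18 at 0.34 and MRPS16 at 0.26. General stress genes (6 of 33, 13 when adjusted over the list alone, adjusted p = 0.453), histones (1 of 10, 5 when adjusted over the list alone, adjusted p = 0.449) and histidine genes (1 of 7, 3 when adjusted over the list alone, adjusted p = 0.256) did too. Methionine and sulfate genes shifted downward (9 of 27 lower, 13 when adjusted over the list alone, adjusted p = 0.0866), with MMP1 at -0.36 and SAM3 at -0.29. Amino acid permeases did so as well (7 of 20, 9 when adjusted over the list alone, adjusted p = 0.235), with MUP1 at -0.27 and TAT1 at -0.26. So did iron regulon genes (5 of 23, 10 when adjusted over the list alone, adjusted p = 0.256), with FRE4 at -0.38, and PAU genes (4 of 22, 15 when adjusted over the list alone, adjusted p = 0.11), with PAU10 at -0.23. Of 274 subtelomeric genes, 28 were lower and 4 higher (34 and 7 when adjusted over the list alone, adjusted p = 0.0866). Of 20 phosphate response genes, 4 were lower and 1 higher (11 and 1 when adjusted over the list alone, adjusted p = 0.235). Of 21 multidrug resistance genes, 1 was lower (6 when adjusted over the list alone, adjusted p = 0.253), and of 13 zinc and copper genes 3 were lower (6 when adjusted over the list alone, adjusted p = 0.296). Of 12 galactose and maltose genes, 0 passed in limma, also 0 when adjusted over the list alone, and 5 had an unadjusted p under 0.05 (adjusted p = 0.465).

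In limma's fit, 574 of 5890 genes differed between the media (9.75%), 323 with the higher change in YC and 251 with the higher change in YEPD. Of these, 8 differed by at least 1.5-fold, or 29 were the values natural logarithms. With arrays 1 and 4, 2 and 5, and 3 and 6 averaged, 3 of the 574 passed, FRE7 (adjusted p = 0.0057), CTR1 (0.007) and FRE1 (0.016). The other single-gene differences thus rest on counting each array as a replicate. The count was 204 without YEPD array 1, 346 without YEPD array 3, 169 without YEPD array 4 and 202 without YEPD array 6. It was 307 without YC array 3, 255 without YC array 6 and 244 without a dye term.

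The genes called in the 2 media overlapped. Of the 101 genes higher in YEPD and the 765 higher in YC, 59 were shared, against 13.1 for independent lists (Fisher's exact test, one-sided p = 1.58e-27), among them CYB5, YHB1, CYC1 and ERG28. Of the lower genes other than SAN1, 18 in YEPD and 696 in YC, 14 were shared, against 2.13 (Fisher's exact test, one-sided p = 1.79e-10), among them YLR108C. FRE7, CTR1, FRE1 and AAP1 were the 4 genes called higher in YEPD and lower in YC. POP7, an RNase P subunit gene (-0.13 and 0.14), was the 1 gene called lower in YEPD and higher in YC. AAP1, an aminopeptidase gene (0.20 and -0.14), and POP7 were named after their values were seen. The media were measured on separate arrays with no array in common. Both lists came from 1 fit, however, with 1 spread and 1 dye term per gene. A gene of small spread is thus more easily called in both media. The values for independent lists and the p-values of Fisher's exact test do not allow for this, nor for genes that move together. Across 5889 genes, which are no independent replicates, the changes in the media hardly correlated (Pearson's r = 0.0989, Spearman's rho = -0.0315). The dye left a stronger mark on the YEPD arrays. Turned values of YEPD arrays of opposite orientation correlated at -0.50 to -0.16 across genes, and those of the same orientation at 0.49 to 0.85. In YC these ranges were -0.03 to 0.65 and 0.09 to 0.46. With a dye term for each medium the counts were 144 in YEPD and 1681 in YC, and with each medium fitted alone 149 and 928.

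**Figure D3:**
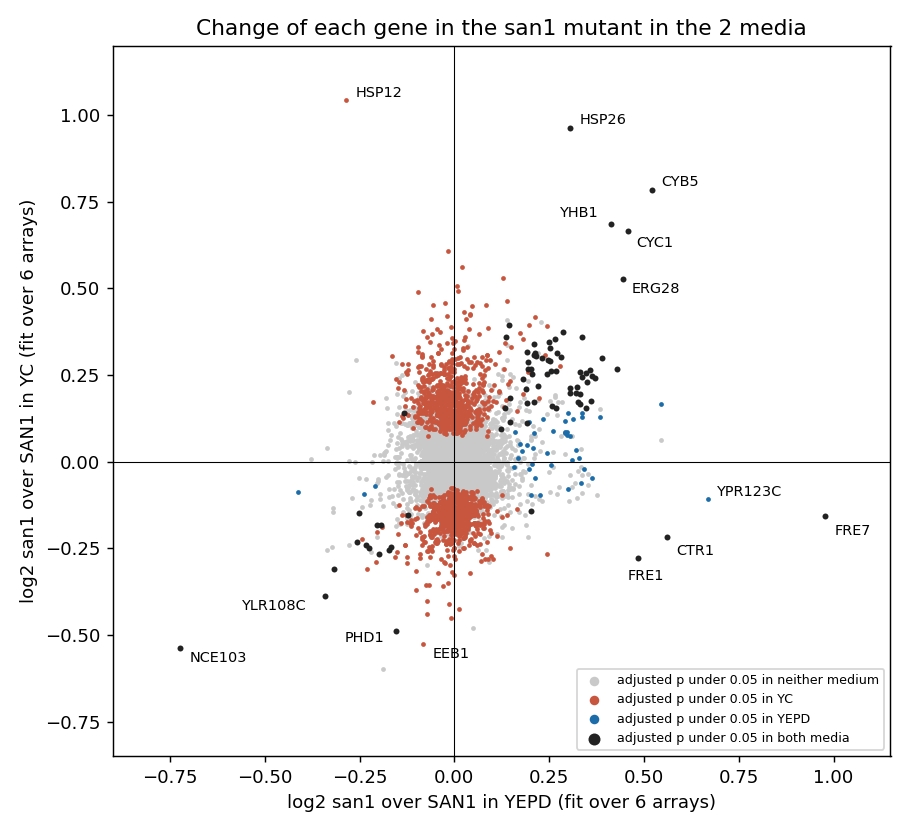
Fitted log2 ratio of san1 over SAN1 in YEPD (horizontal axis) and in YC (vertical axis) of each gene tested except SAN1, coloured by whether the gene passed an adjusted p of 0.05 in neither medium, in YEPD, in YC or in both. CYB5, YHB1, CYC1 and ERG28 lay in the upper right, FRE7, CTR1 and FRE1 in the lower right, and HSP12 at -0.28 and 1.04 in the upper left.

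Over both media together, the genes changed in the same way on every array that measured them were led by CYB5 (0.65, SE 0.041, adjusted p = 1.7e-06), HSP26 (0.63, SE 0.044, adjusted p = 2.3e-06) and CYC1 (0.56, SE 0.05, adjusted p = 1.5e-05). YHB1 (0.55, SE 0.024, adjusted p = 3e-08) and ERG28 (0.49, SE 0.031, adjusted p = 1.8e-06) came next. YGR164W (0.36), SSA1 (0.35), HMG1 (0.35), ASP3-3 (0.34), SCM4 (0.33) and HSC82 (0.32) followed. YGR164W and ASP3-3 were measured on 11 arrays and the others named here on 12. YLR108C (-0.36, SE 0.026, adjusted p = 2.9e-06), PHD1 (-0.32, SE 0.025, adjusted p = 4.6e-06) and TIR1 (-0.31, SE 0.036) were lower. ARN2 (-0.27, SE 0.041), MUP1 (-0.24), PEX7 (-0.23), PDR5 (-0.21) and PYC1 (-0.21), encoding a pyruvate carboxylase, were lower as well. Hsf1-dependent chaperones (15 of 25 higher, 18 when adjusted over the list alone) kept their call with an estimated correlation (adjusted p = 1.2e-10). So did Y' helicases (7 of 7, 7 when adjusted over the list alone, adjusted p = 1.35e-05) and ergosterol genes (12 of 25 higher and 3 lower, 14 and 6 when adjusted over the list alone, adjusted p = 0.000134), and the other 15 of 18 lists did not. The contrast over both media is the mean of the 2, so a gene can pass through its change in 1 medium alone. In limma's fit 611 genes passed, 346 higher and 265 lower. Of these, CYB5, HSP26, SAN1 and NCE103 changed by at least 1.5-fold, and 8 genes would were the values natural logarithms. NCE103 (-0.63), not below 0 on each YC array, was named after its value was seen. The count was 197 with arrays 1 and 4, 2 and 5, and 3 and 6 averaged and 373 without a dye term. It was 400 without YEPD array 3, 347 without YEPD array 5, 398 without YEPD array 6 and 369 without YC array 6.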

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

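The dye tests of all 3 patterns, the test of growth states, the Mac1 test and the tests of inner subtelomeric genes were chosen after the results they measure were seen. The stress dye test, the growth test and the subtelomeric test were reworded after a first run. The first stress dye test, on the lowest array median (-0.04), left the question undecided. The first growth test, on the lower quartile of the ribosome biogenesis genes (-0.09), would have counted against it, and the array medians then showed these genes moving against the stress genes. The first subtelomeric test joined the media and gave a mixed answer. The splits of array averages and the list tests of inner genes with an estimated correlation were added last, and the latter turned the YEPD answer from a rise to an open one. The tests of pairs, of shared sequence and of the other splits were written down before they were run, though after the gene and list results were known.

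Among 195 sets of 6 or fewer values examined, 4 had a single array far from the others, where chance alone gives about 1 in 20. RPN5 was at 0.09 on YEPD array 2, against -0.10 to -0.03 on the others, and SUN4 at -0.40 on YC array 4, against -0.23 to -0.16. The histone median was -0.02 on YC array 1, against 0.17 to 0.27, and the proteasome median 0.20 on YC array 4, against 0.06 to 0.11.

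For 57 of the genes in the text, the effect of san1 differed between the media in limma's test of the difference. It did so, too, for AAP1 (-0.34), HMRA2 (0.31) and POP7 (0.28), which are not among the 57. With arrays n and n plus 3 averaged, limma's fit still called only FRE7 (adjusted p = 0.0057), CTR1 (0.007) and FRE1 (0.016) for the difference. HSP12 (0.06), HSP26 (0.06) and CTT1 (0.19), for example, were not called. The other differences listed here thus rest on counting each array as a replicate. Some of the genes entered the text because their difference was among the largest. The stress and chaperone genes HSP12 (1.33), HSP26 (0.66), RTC3 (0.62), STF2 (0.59), MSC1 (0.54), FMP16 (0.51), CTT1 (0.50), STF1 (0.48), PBI2 (0.47), SSA4 (0.40), PNC1 (0.36), NTH1 (0.22) and CPR6 (0.22) had the higher effect in YC. So did SEM1 (0.47), RPN8 (0.35), RPN5 (0.32), MRP8 (0.38), RSM18 (0.34), MRPS16 (0.26), MTD1 (0.44), HHF1 (0.33), CIS1 (0.32), YHB1 (0.27), ERG20 (0.23) and HIS7 (0.20). Genes at the mating-type loci did too: YCR097W-A (0.46), MATALPHA2 (0.40) and HMLALPHA2 (0.24). The effect was lower in YC for the metal genes FRE7 (-1.14), CTR1 (-0.78), its neighbour YPR123C (-0.78), FRE1 (-0.76), ARR3 (-0.41), FET4 (-0.38) and FRE4 (-0.38), with FET4 at -0.20 without YC arrays 1 and 4. It was lower for the transport genes PHO89 (-0.44), MMP1 (-0.36), SAM3 (-0.29), MUP1 (-0.27), TAT1 (-0.26), GNP1 (-0.19) and THI7 (-0.17). It was lower for EEB1 (-0.44), IRC7 (-0.40), MMO1 (-0.37), PHD1 (-0.33), EOS1 (-0.29), MKC7 (-0.28), PAU10 (-0.23), SAG1 (-0.21), THI13 (-0.20), SUN4 (-0.18), IPT1 (-0.16) and PAU15 (-0.15). It was lower, too, for the reading frames YCL046W (-0.51), YDL096C (-0.40) and YGR164W (-0.38).

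General stress genes rose in YC with like means in the 2 dye orientations (0.24 and 0.26), which argues against a dye bias of the genes. Leaving out arrays 2 and 5 lowered their median from 0.23 to 0.09, so this pair carries most of it. On that pair the stress median was 0.53 and the ribosome biogenesis median -0.18, while arrays 1 and 4 had -0.03 and 0.20. Cultures in different growth or stress states could thus give the stress pattern apart from san1, and this stays open. An effect of san1 that varied between cultures stays open too and was not tested. Not every stress gene followed the pattern of the pairs. On YC arrays 1 and 4 HSP12 was at 0.92 and 1.39, whereas CTT1 was at 0.24 and 0.17.

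FRE7, CTR1 and FRE1 had no value under 0.39 on the YEPD arrays of either orientation. They were named among genes with the same sign on every array that measured them. A positive value in both orientations was thus fixed by that choice, so this test cannot decide on a dye bias. The mean of these genes, 0.67, was at least 0.64 without any pair of arrays, so no single pair carries the rise. A wider rise of the targets of the copper regulator Mac1 may lie behind it, but REE1 rose (0.31, adjusted p = 0.041) and CTR3 was not shown to (0.10, adjusted p = 0.67), which leaves this undecided. A different copper supply of the paired cultures, or an effect of san1 that depends on the medium, was not tested and stays open.

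The Y' helicase genes had a median of at least 0.13 on each of 12 arrays, which argues against a dye bias. Their residuals correlated at a median of 0.25, which signal shared between near-identical copies could give, as could common regulation, so the number of copies that rose cannot be told apart. In YEPD the inner genes of the chromosome ends had a median of 0.03 (2.38% of them higher, against 1.71% of all genes, list test unadjusted p = 0.0163, or 0.0705 with an estimated correlation), so a rise of subtelomeric genes in general stays open there. In YC their median was -0.04, with 10 risen and 30 fallen of 168, against 765 higher and 697 lower of all 5890 genes. The list test gave an unadjusted p of 0.00741 downward, or 0.0438 with an estimated correlation. This argues against a rise in YC that reaches these inner genes. The outermost 1 to 4 genes of an end, Y' helicases among them, had 25 risen and 9 fallen of 106 in YC (median 0.01). A rise limited to them is thus not covered. The whole subtelomeric list did not shift in YC (list test adjusted p = 0.512). A different number of Y' elements in the mutant strain was not tested.

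The 6 arrays of a medium allow 10 splits by sign into equal groups, too few for a share under 0.05. The real split, 1 of the 10, gave 120 genes in YEPD and the highest other 0, and in YC the real split, again 1 of 10, gave 1462 and the highest other 101. For the difference between media, the real split was set beside others drawn at random from those possible, 100 in all. Of the 100, 1, the real one, gave as many as 574 genes, with 77 in the highest other. This is a share under 0.05 if each array counts as a replicate. Any difference between the YEPD and the YC arrays, whatever its cause, could single out the real split in this way. The share therefore does not tell a medium-dependent effect of san1 from another difference between these arrays. If arrays n and n plus 3 hold the same RNA, their 6 averages allow 10 splits, too few for a share under 0.05. There the real split gave 3 genes and the highest other 0.

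Over both media, the real split was set beside others drawn at random from those possible, 100 in all. Of these, 4 gave at least the real 611, with 982 in the highest other. The 3 others that did so kept the YC arrays turned as labelled and turned YEPD arrays against their labels, as did 3 more that gave fewer genes, down to 71. Of the 6 drawn that kept YC as labelled, 3 thus reached 611. The result of 4 in 100 depends on how many such splits were drawn, so it is not read as a share under 0.05. Nor does the count say anything about the labels of the YEPD arrays. The contrast is the mean of the media, so a gene can pass through its change in YC alone, where 1462 passed. Only 78 genes other than SAN1 were called in each medium by itself, in either direction. Why some splits gave more genes than the real one was not tested.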

How the results depend on the processing

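Averaging YEPD arrays 4 and 6, and leaving out YC arrays 1 and 4 together, were chosen after seeing the data. Of 391 results for named genes, 203 kept their call and direction under each alternative in which the gene could be tested. The alternatives meant are those run gene by gene, except the size threshold. Under these, 0 of the 391 reversed. As nearly all were named because they were called, many with 1 sign on every array, few reversals could occur. The opposite sign of arrays 4 to 6 was run for counts only and ended all calls in YC and for the difference. Averaging arrays n and n plus 3 left 65 genes in YEPD, 816 in YC, 3 for the difference and 197 over both media, with fewer values per gene by construction. Without a dye term the difference had 244 genes and both media 373. The YC arrays alone gave 928 genes in YC. Array number as a fixed replicate block, although the numbers do not pair the media, gave 905 in YC, 46 for the difference and 269 over both, and as a random block 318 for the difference. At least 1.5-fold changes numbered 4, 7, 8 and 4 in YEPD, YC, the difference and both. With arrays 4 to 6 taken with the opposite sign, limma called 922 genes in YEPD, 0 in YC, 0 for the difference and 760 over both media, more than the 611 as labelled. In YC 617 and for the difference 743 then had an unadjusted p under 0.05. The strain effect and the dye effect change places by construction. Averaging YEPD arrays 4 and 6 gave 201 for the difference. With an estimated correlation 5, 3, 2 and 3 lists passed. Leaving out each array in turn gave 81 to 135 genes in YEPD, 988 to 1568 in YC, 169 to 800 for the difference and 347 to 742 over both media, and 9 to 12, 16 to 21, 14 to 22 and 13 to 19 lists. Except where construction is named, the cause was not tested. Signal over background is not in the deposited table, so its limits could not be examined.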

Other observations

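The genes and the test in this part were chosen after the gene results were seen, and the prediction for the Hap1 targets was written before that test was run.

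At the mating-type loci, transcripts in YC were higher in san1 on 6 of 6 arrays for MATALPHA2 (0.31), HMLALPHA2 (0.17), HMRA2 (0.23) and YCR097W-A (0.38). The copies share sequence, so which locus gave the signal is uncertain. Of other genes at or next to these loci, HMRA1 rose in YC too (0.25) and VBA3 fell (-0.11). Among those that did not pass were the frames YCL065W (0.02), YCL068C (-0.01) and YCR041W (-0.06). MATALPHA2 and HMLALPHA2 are 2 of the 6 genes in the alpha-specific list, which did not shift in YC (list test adjusted p = 0.908). Of the other 4, 0 rose, SAG1 (-0.24) and STE3 (-0.21, and -0.14 without YC arrays 1 and 4) fell, and 2 did not pass.

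CYB5, CYC1, YHB1 and sterol genes rose in both media, and a candidate explanation was a rise of Hap1 targets, Hap1 being a heme-responsive regulator. The further targets CYT1, CYB2, ROX1, NCP1 and DLD1 had a median change of 0.04 over both media. In YEPD the median was 0.08 and CYT1 came nearest to passing by itself (0.29, adjusted p = 0.0501). The list test there gave an unadjusted p of 0.0392, or 0.0606 with an estimated correlation. In YC DLD1 rose (0.17, adjusted p = 0.0086), NCP1 fell (-0.12, adjusted p = 0.019) and the list test gave an unadjusted p of 0.752. This leaves the hypothesis undecided.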
